A study of Homo sapiens with 26 samples.

How the data were processed

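Single-cell DamID was analysed in 26 cells of the human line KBM7, clone 5-8, all labelled haploid (1N) and Dam alone. Per the labels' protocols, Dam methylation was induced with 0.5 nM Shield1 for 15 h. Cells in the smallest 2% by scatter that were positive for both Fucci cell cycle markers were sorted singly into plates. Methylated DNA was then digested with DpnI, ligated to adapters and amplified with 21 extension steps. Reads were handled with cutadapt and Bowtie2 2.1.0 and the genome build was hg19, per the submitters' processing notes. How reads were counted, which bins were masked and how the expectation was built are not given in the sources used here.

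The deposited values are a linear ratio per 100 kb bin and cell, read as observed over expected from the file's name and from cell means between 0.925 and 0.997 over used bins. The same 3792 of 30376 bins had no value in every cell, among them all of chromosome 8 and chromosome 15 from 61000001 to 89900000. A further 253 bins were 0 in all cells and were left out, which left 26331 used bins. Every one of the 26 columns was matched to 1 sample by its number.

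Within a bin, the ratios of all cells were whole multiples of a step. The smallest whole numbers that give the ratios were recovered, with a largest distance from a whole number of 2.42e-13 (tolerance 0.001), together with a relative expectation per bin. For a bin with counts in few cells, these numbers fix its count and expectation only up to a common factor. Recovered totals ran from 20182 to 178941 per cell, or 0.766 to 6.80 counts per used bin, so a single bin in a single cell carries a large counting error and values were averaged over chromosomes, blocks or cells. Counts of every pair of cells were compared over 1 Mb windows by a heterogeneity chi-square, a check added after the data were seen.

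The level of a chromosome in a cell was its mean ratio over the mean of all other autosomes. Ends were the terminal 5 Mb, without the low-coordinate end of 13, 14, 15, 21 and 22:9. Gene-dense and gene-poor chromosomes came from textbook knowledge. Positive bins, runs, similarity between cells and correlation by distance were computed as described with the results, with 100 circular shifts or 100 permutations of cells within bins, 20 shuffles for runs, and pairs on different chromosomes drawn at random from 200000 draws. These definitions, the chromosome classes and the rule for named regions (the 10 highest and 10 lowest regions after merging adjacent ranked bins, the lowest among bins positive in at least 1 cell, and each chromosome past the threshold) were fixed before the data were examined. So were the alternatives on bin filters, capping at the 99th percentile, the share of bins at 1 or more, the value that defines positive, log2 scales with 0.1 added, and leaving out the 6 cells of lowest coverage.

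Sign-flip permutation tests over cells had been planned for the level comparisons. They are not reported, because all cells came from 1 clone and cells of 1 clone are not replicate cultures. In their place the number of cells on each side is given, and a chromosome was placed on a side at 80% of the cells (21 of 26), a rule set after the data were seen. Also chosen after the data were seen were summed counts over summed expectation, leaving out the 903 bins with an expectation under 0.5 times the median, leaving out cell 22, leaving 22:9 out of the gene-dense class, thinning every cell to 20000 counts, dividing each cell by its mean on each chromosome, and the values for arms, blocks and bins near centromeres.

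The planned comparisons of chromosome 8 and of the chromosome 15 segment could not be made, since no bin there had a value. Gene density, gene lists, GC content and GATC density were not analysed here. The gene table used for this work is of another genome build, so regions are named by position alone.

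The procedures were tested on simulated counts drawn with the real expectations and cell depths. Whole counts were recovered exactly in all cells for 99.98% of 26294 bins. The simulated levels of 1.3, 0.8, 1.1 and 0.9 on chromosomes 1, 4, 7 and 12 were all placed on the right side, within 2.90%. Of 18 chromosomes simulated without a shift, 3 were placed below 1, at levels between 0.973 and 0.989, because a level is relative to the raised chromosomes too. Data simulated with independent bins gave a correlation of 7.07e-05 at 20 Mb and a run ratio of 1.00. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.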

Results

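DamID maps chromatin that an adenine methyltransferase can reach: the bacterial enzyme Dam methylates adenine in GATC sequences, and a methyl-dependent digestion followed by PCR recovers the marked fragments. Here 26 single cells of KBM7, a human leukaemia cell line with a nearly haploid genome, were profiled, all from clone 5-8 and all labelled as carrying Dam that is not fused to another protein. Unfused Dam is commonly used as a reference for a fusion protein and marks accessible chromatin. The title of the series names lamin B1, a protein of the nuclear lamina, whereas its design text and the label of every sample name Dam alone, and the sample labels were followed. The design text counts 124 cells and 26 were analysed here. All 26 cells form 1 group from 1 clone, so the comparisons are between parts of the genome inside the same cells, each SD is a spread between cells of that clone, and no p-value was computed across cells.

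The values were ratios of observed over expected signal in bins of 100 kb. Of 30376 bins, 26331 had a value above 0 in at least 1 cell and were used. The whole counts behind the ratios totalled between 20182 in cell 21 and 178941 in cell 1, with a median of 42448.5. The share of used bins above 0 ran from 34.3% in cell 22 to 94.9% in cell 1. The file joins parts of chromosomes 9 and 22 into 2 derivative chromosomes, 9:22 and 22:9, the products of the translocation that KBM7 carries. Chromosome 8 had no value in any of its 1464 bins. On chromosome 15 the 289 bins from 61000001 to 89900000 (hg19) had none either. KBM7 is known to carry an additional copy of both parts, and their levels were not analysed here.

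The first question was how evenly Dam marked the chromosomes. By the ratio of observed over expected signal it did not mark them evenly. Chromosome 19, the most gene-dense human chromosome, had the highest level, 1.66 ± 0.494 (SD, n = 26 cells) times the mean of all other autosomes, and was above 1 in 25 of 26 cells. Chromosome 17 followed at 1.48 ± 0.214 and the derivative 22:9 at 1.31 ± 0.258, each above 1 in 25 cells. Chromosome 4, which is gene-poor, was lowest at 0.708 ± 0.133, below 1 in 25 cells, and chromosome 13 stood at 0.737 ± 0.105, below 1 in all 26.

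A chromosome was placed on a side when at least 21 of the 26 cells lay on that side of 1. Besides 17, 19 and 22:9, this placed above 1 chromosome 16 at 1.23 ± 0.182 (22 cells), chromosome 1 at 1.16 ± 0.124 (23 cells), the derivative 9:22 at 1.16 ± 0.229 (21 cells) and chromosome 20 at 1.15 ± 0.219 (22 cells), making 7 of the 22 chromosomes. Below 1 were 8: besides 4 and 13, the X chromosome at 0.810 ± 0.0959 (25 cells), chromosome 18 at 0.819 ± 0.155 (22 cells), chromosome 5 at 0.878 ± 0.149 (21 cells), chromosome 2 at 0.897 ± 0.119 (23 cells), chromosome 7 at 0.904 ± 0.0955 (23 cells) and chromosome 3 at 0.913 ± 0.133 (21 cells). Chromosome 3 was the least secure of these, keeping its side in 3 of 9 alternative settings. Chromosomes 6, 10, 11, 12, 14, 15 and 21 were on neither side. Chromosome 6 had a mean of 1.02 ± 0.271 with single cells between 0.783 and 1.97, and chromosome 14 a mean of 0.982 ± 0.198 with a highest cell at 1.77.

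Summed over the 26 cells, chromosome 19 held 46295 counts, or 1.70 times the autosomal mean per unit of expectation, with an exact 95% Poisson interval from 1.68 to 1.72. The same quantity was 0.729 on chromosome 4 (0.724 to 0.735, 76369 counts). These intervals cover counting error only, and whether PCR copies of a fragment were told apart is not given in the sources used here.

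**Figure D1:**
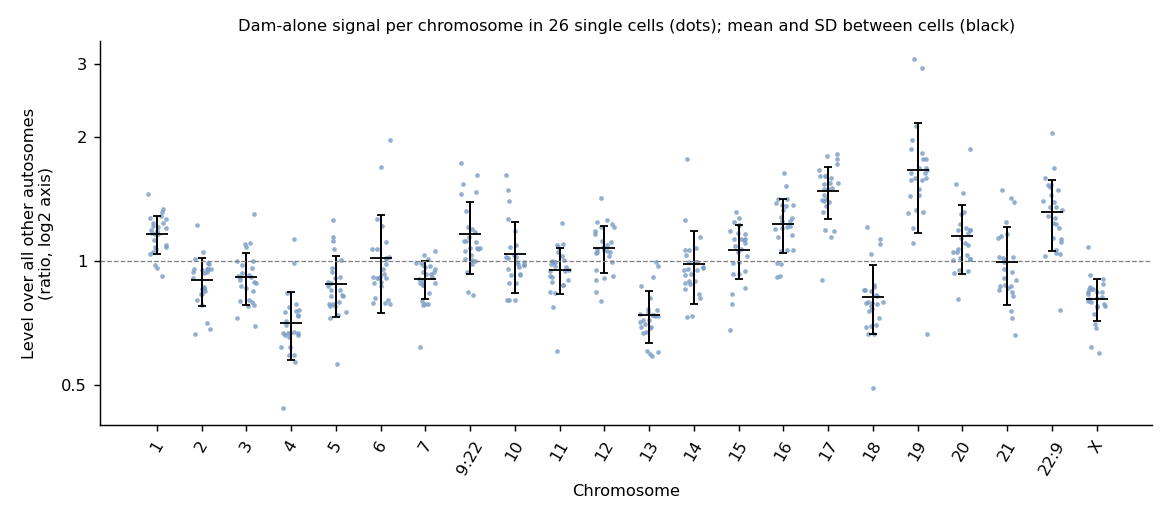
Level of each chromosome (vertical axis, ratio to the mean of all other autosomes, log2 axis) in each of 26 single cells (dots), with the mean and SD between cells (black bars). Chromosomes 17, 19 and 22:9 lie above 1 in 25 cells each, chromosome 13 lies below 1 in all 26, and chromosome 6 ranges from 0.783 to 1.97.

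The second question was whether gene-rich chromosomes as a class were marked more than gene-poor ones. By the ratio of observed over expected signal they were, in all 26 cells. GC content, GATC density and the DNA copy number of the sorted cells, which were selected by cell cycle markers, were not analysed. Their share in this difference and in the chromosome levels was not tested. Gene-dense chromosomes 16, 17, 19, 20 and 22 (taken as 22:9, 2831 bins in all) had a mean ratio of 1.32 ± 0.147 (SD, n = 26), against 0.776 ± 0.0737 over the 5335 bins of the gene-poor chromosomes 4, 5, 13 and 18. The mean log2 ratio between the classes was 0.77 ± 0.28, a 1.70-fold difference. Cells differed in its size, from a log2 ratio of 0.14 in cell 22 to 1.26 in cell 13. Chromosome 22 entered the gene-dense class only as the derivative 22:9 (133 used bins), which also holds sequence of chromosome 9. The rest of chromosome 22 lies on the derivative 9:22, outside the class. The mean log2 ratio was 0.77 without 22:9 too.

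Chromosome ends had slightly higher ratios than interiors, with large differences between chromosomes. With every autosome weighted equally, the terminal 5 Mb (1815 bins) had a mean ratio of 1.09 ± 0.0981 and the interiors 1.03 ± 0.0343. The log2 ratio was 0.09 ± 0.11 and above 0 in 24 of 26 cells. The lowest cell was cell 22 at -0.30. The high-coordinate end of 14, the only end used there, stood out at 1.38 ± 0.420 against 0.936 ± 0.189 on the rest (higher in 25 cells). That of 21, also the only end used, was at 1.28 ± 0.311 against 0.922 ± 0.212 (23 cells). On chromosome 3 the ends were at 1.16 ± 0.205 against 0.883 ± 0.122 (25 cells), and on chromosome 16 at 1.45 ± 0.300 against 1.15 ± 0.172 (24 cells). The opposite held on chromosome 10, whose ends were at 0.796 ± 0.194 against 1.03 ± 0.183 (lower in 23 cells), and on 22:9, whose high-coordinate end was at 1.01 ± 0.277 against 1.44 ± 0.276 (lower in 25 cells). In all, ends were higher in at least 21 cells on 9 of 21 autosomes, lower on 5 and on neither side on 7.

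The next comparisons asked how far single cells share one map. A bin was called positive in a cell at a ratio of 1 or more, which held for 36.0% ± 2.61 of used bins per cell. Positive in at least 80% of the cells were 1478 bins (5.61% of used bins), where 100 random circular shifts of each chromosome in each cell gave 2 to 14. Positive in at most 20% of the cells were 8808 bins (33.5%), where the shifts gave 2015 to 2194. Only 24 bins were positive in all 26 cells and 234 in none. Both counts depend on the value that defines positive and on depth. At 2 or more, 121 bins were positive in at least 80% of cells, and at 0.5 or more, 4686, both above all shifts. Positive in at most 20% of cells were 1806 bins at 0.5 or more, above all shifts, but 19781 at 2 or more, below the mean of the shifts at 21066. Without the 6 cells of lowest coverage 2319 bins were positive in at least 80% of cells. With every cell thinned to 20000 counts 5109 were positive in at most 20%. Both were above all shifts. All cells share 1 expectation per bin, which the shifts put out of alignment too, so its part in these counts is not measured by them.

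Bins shared by most cells were unevenly spread over the chromosomes. They made up 20.9% of the used bins of chromosome 19 and 13.5% of those of chromosome 17, against 1.36% on chromosome 13 and 1.55% on chromosome 4. Their share did not always go with the chromosome level: it was 6.02% on 22:9, whose level was high, and 8.40% on chromosome 12 and 6.75% on chromosome 6, which were on neither side. Bins positive in few cells made up 49.0% of chromosome 4, 45.4% of chromosome 13 and 43.9% of the X chromosome, but 8.59% of chromosome 19. The 2 longest unbroken blocks of shared bins were on chromosome 12 and spanned 8 bins each, at 6400001 to 7200000 and at 56300001 to 57100000 (hg19). Their ratios relative to the cell mean were 2.66 ± 1.02 and 2.78 ± 0.784 (SD, n = 26). A block of 6 bins on chromosome 1, at 28400001 to 29000000, averaged 3.91 ± 0.865. The longest block positive in few cells spanned 45 bins on chromosome 3, at 162400001 to 166900000, with a relative ratio of 0.298 ± 0.163. Chromosome 1 at 79200001 to 82600000 (34 bins) averaged 0.354 ± 0.179 and chromosome 10 at 55400001 to 58700000 (33 bins) averaged 0.367 ± 0.297. Blocks were listed after the data were seen.

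**Figure D2:**
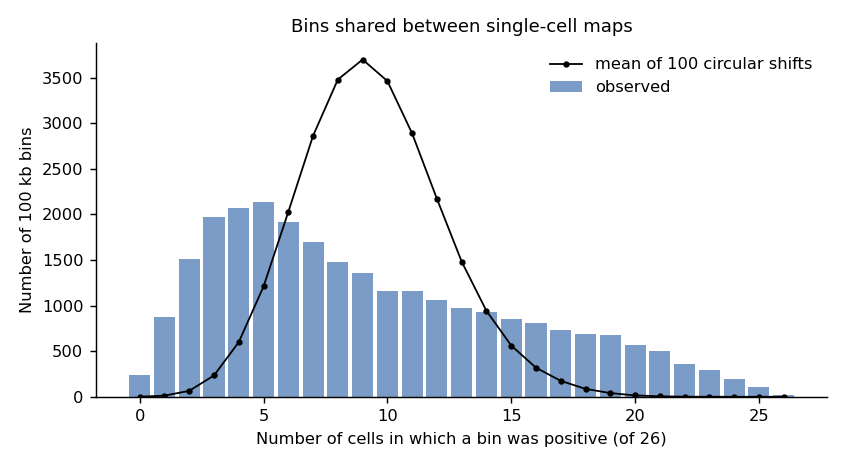
Number of 100 kb bins (vertical axis) that were positive in a given number of the 26 cells (horizontal axis), observed (bars) and as the mean of 100 circular shifts (line). The observed distribution is wider at both ends, with 1478 bins positive in at least 80% of cells against at most 14 in any shift.

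Single bins were ranked by their mean ratio relative to the cell mean. The 10 highest were single bins with a very small expectation, between 0.316% and 3.80% of that of the median bin. The highest, on chromosome 1 at 148000001 to 148100000, averaged 22.5 ± 73.8 from 3 counts in 3 cells, and the next, on 9:22 at 40700001 to 40800000, averaged 18.8 ± 78.0 from 2 counts. Bins on chromosome 10 at 17800001 to 17900000 and on chromosome 1 at 148200001 to 148300000 owed their rank to 1 cell each. Counts and expectations of bins with values in few cells are the smallest that give the ratios. The ranking was therefore repeated, after the data were seen, without the 903 bins whose expectation was under 0.5 times the median. First then came 9:22 at 146800001 to 147000000 (positions along the derivative), at 6.75 ± 3.71 from 669 counts over 2 bins, with a positive bin in all 26 cells. Chromosome 5 at 43000001 to 43100000 followed at 6.33 ± 4.10, and chromosome 1 at 28800001 to 28900000 was at 5.30 ± 2.87, both positive in all 26 cells. On the X chromosome, which was low as a whole, the bin at 64900001 to 65000000 averaged 4.97 ± 3.15 and was positive in all 26 cells.

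Among bins positive in at least 1 cell, the lowest was on chromosome 11 at 89000001 to 89100000, at 0.0512 ± 0.261 from 1 cell. Of the 10 lowest, only 2 had a recovered expectation above 0.5 times the median. They were on chromosome 12 at 87100001 to 87200000 (0.0712 ± 0.25, 5 counts) and on chromosome 4 at 97300001 to 97400000 (0.0737 ± 0.255, 3 counts). Both were positive in 1 cell each. For a bin with a value in 1 cell the recovered expectation is a lower bound, so others of the 10 may also lie above that limit.

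Within a cell, positive bins lay next to each other more than their number alone would give. The mean run of consecutive positive bins was 2.02 ± 0.265 bins (SD, n = 26), against 1.61 ± 0.0697 after shuffling bins within chromosomes. Observed runs were longer in all 26 cells, with ratios from 1.11 in cell 21 to 1.73 in cell 1. Cells 21 and 1 also had the lowest and highest total counts. With every cell thinned to 20000 counts, the mean log2 ratio went from 0.32 ± 0.15 to 0.20 ± 0.059.

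Cells resembled each other more than shifted maps did. The mean Spearman correlation of a cell with the other cells, across bins, was 0.269 ± 0.0628, against at most 0.0218 in 100 circular shifts, and fell to 0.169 with every cell thinned to 20000 counts. Bins are not independent replicates. All cells also share 1 expectation per bin, and the shifts break that alignment too. They therefore do not show how much of the resemblance comes from the shared expectation. Without the bins of low expectation the mean correlation was 0.267. The highest of the 325 pairs reached 0.508. No pair of cells had identical values, and over 1 Mb windows the chi-square of the counts divided by its degrees of freedom was lowest for cells 9 and 16, at 1.68, where counting noise alone gives about 1. Cell 22 stood apart at 0.0510. The next lowest was cell 21 at 0.191 and the highest cell 1 at 0.364. Part of that range goes with depth: with thinned counts the cells other than cell 22 ran from 0.150 to 0.215.

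The last comparison asked whether bins go up and down together from cell to cell. Neighbouring bins did so weakly. The mean Pearson correlation across the 26 cells was 0.111 for bins 0.1 Mb apart, 0.0462 at 1 Mb, 0.0259 at 10 Mb and 0.0199 at 20 Mb. No permutation of cells within bins, out of 100, exceeded 0.0035 at 0.1 Mb or 0.0030 at 20 Mb. Bins on different chromosomes averaged 0.0014, with permutations up to 0.0013, but this value did not hold: it was -0.00031 without the 6 cells of lowest coverage, -0.00016 with every cell thinned to 20000 counts, both inside the permutations, and 0.0574 on log2 values. Bin pairs overlap and are not independent. At 0.1 Mb the correlation was 0.0699 without cell 22 and 0.0558 without the 6 cells of lowest coverage, of which cell 22 is one.

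**Figure D3:**
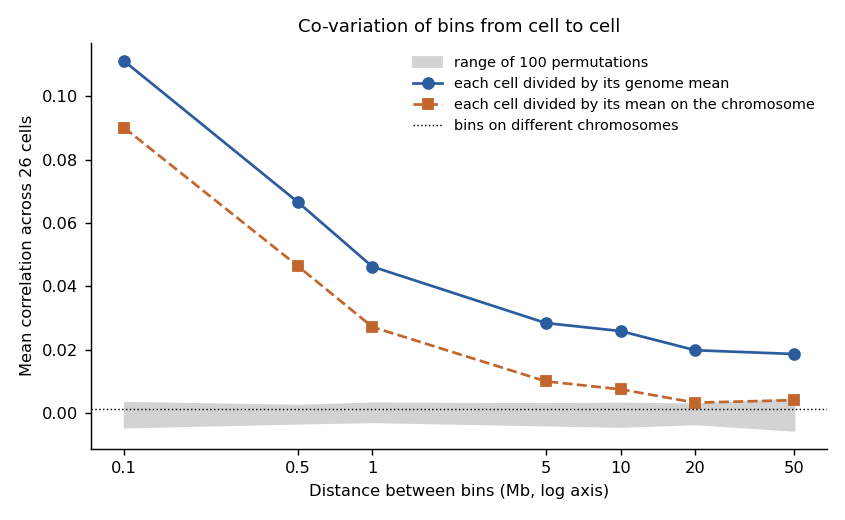
Mean correlation across 26 cells (vertical axis) of pairs of bins at a given distance on one chromosome (horizontal axis, Mb, log axis), with each cell divided by its genome mean (circles) or by its mean on the chromosome (squares). The grey band is the range of 100 permutations for the circles and the dotted line marks pairs on different chromosomes at 0.0014. Circles fall from 0.111 at 0.1 Mb to 0.0199 at 20 Mb and squares from 0.0900 to 0.0034.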

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

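Of 132 recomputed values that answer a comparison, 124 met the criterion set for their kind: counts stayed within 1.5 times the main count, means over cells within 1 SD, and similarities and correlations by distance above all shifts or permutations, whatever their size. Some of these could not fail. Keeping bins that were 0 in all cells cannot alter a correlation by distance. A bin positive in at least 80% of cells passes both bin filters, so that count stayed at 1478. On log2 values even pairs on different chromosomes, at 0.0574, lay above all permutations. Thinning, the expectation filter, summed counts, leaving out cell 22, leaving out 22:9 and division by chromosome means were chosen after the data were seen. The gene-dense over gene-poor log2 ratio stayed between 0.70 and 0.83 over 10 alternatives, the ratio of ends over interiors between 0.07 and 0.13 over 9, and that of runs over shuffled between 0.20 and 0.33 over 8. The similarity between cells ran from 0.169 with thinned counts to 0.311 without the 6 cells of lowest coverage. Between 6 and 8 chromosomes were placed above 1 and 7 or 8 below. Chromosome 3 lost its side in 6 of 9 alternatives, while 7, 9:22 and 20 each kept theirs in 8 of 9. All 198 recomputed chromosome levels moved by less than the SD between cells, which could not have been otherwise in the settings that leave out cells.

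Bins positive in at least 80% of cells numbered 2319 without the 6 cells of lowest coverage, 4686 with positive at 0.5 or more and 121 with positive at 2 or more, each above all shifts. Bins positive in at most 20% of cells numbered 1806 at 0.5 or more, 19781 at 2 or more and 5109 with thinned counts. At 2 or more their number was below the mean of the shifts, 21066. The correlation between bins on different chromosomes, 0.0014, changed sign to -0.00031 without the 6 cells of lowest coverage and to -0.00016 with thinned counts, and was 0.0574 on log2 values. The cause was not tested. Correlations by distance stayed above all permutations but changed in size: at 20 Mb the value was 0.0698 on log2 values and 0.0034 after division by chromosome means. In 9 of the 20 regions named by rank, the value rests on 1 cell. The recovered count of such a bin is 1 by construction, whatever the true count. Leaving out chromosome 8 changes nothing, since it had no values, and the alternatives for chromosome 8, the chromosome 15 segment, gene density and gene lists were not run. No paired analysis was possible because there is no second group to share replicate numbers, while ratios between parts of the genome were taken within each cell.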

Other observations

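Arms of one chromosome differed in ways that chromosome means hide, in values chosen after the data were seen. No centromere annotation was used. Arms were split at the longest stretch of bins without a value, after nearby stretches were joined and the chromosome 15 segment was set aside. On chromosome 6, which was on neither side as a whole, the p arm had a mean ratio of 1.28 ± 0.328 (SD, n = 26 cells) and the q arm 0.838 ± 0.213, with the p arm higher in all 26 cells. Chromosome 5 ran the other way, with 0.690 ± 0.187 on the p arm and 0.926 ± 0.155 on the q arm (q higher in 25 cells). So did chromosome 20, with 0.936 ± 0.190 and 1.26 ± 0.238 (q higher in 25 cells). On chromosome 16 the p arm was higher in 25 cells, at 1.34 ± 0.216 against 1.08 ± 0.156, and so was Xp, at 0.873 ± 0.106 against 0.742 ± 0.0935. Of 17 chromosomes with both arms measured, 6 had the p arm higher in at least 21 cells, 4 the q arm, and 7 neither.

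Bins within 5 Mb of the centromere gap also differed by chromosome, again in values chosen after the data were seen and without bins of low expectation. The gap is the stretch without values at which arms were split. As few as 12 bins were near it, on chromosome 15. They were higher than the rest in at least 21 cells on 10 of 19 autosomes, lower on 5 and on neither side on 4, and the mean log2 ratio was 0.05 ± 0.09, above 0 in 19 of 26 cells. On chromosome 19 they stood at 0.877 ± 0.265 against 1.78 ± 0.521 on the rest, lower in all 26 cells. Chromosome 3 had 0.481 ± 0.166 against 0.922 ± 0.121 (lower in 25 cells), and chromosomes 6 and 12 were lower there in all 26 cells. Higher values near the gap were found on chromosome 14, at 1.59 ± 0.487 against 0.915 ± 0.177 (25 cells), on chromosome 18, at 1.18 ± 0.290 against 0.752 ± 0.151 (25 cells), and on chromosome 20, at 1.49 ± 0.424 against 1.06 ± 0.185 (25 cells).

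Single cells had whole chromosomes far above their level in the other cells, a pattern whose tests were written after these levels, but before the tests' own results, were seen. Ratios were taken relative to the median of the other cells and to the median chromosome of the same cell. Of 550 pairs of a chromosome and a cell, 16 reached 1.5-fold, in 7 of the 25 cells other than cell 22. Chromosome 6 was at 2.33-fold in cell 3 (4915 counts) and at 2.08-fold in cell 10. The 95% Poisson interval in cell 3 was 2.26 to 2.39, for counting error only, and whether PCR copies were told apart is not given. Chromosome 14 was at 2.17-fold in cell 10, and chromosome 19 at 2.07-fold in cell 3 and 1.99-fold in cell 13. Of the 16 pairs, 9 were at 1.66-fold or less. High counts in a few bins are argued against, since the lowest median over 5 Mb windows among the 16 was 1.47, and so is a tilt of the cell between gene-dense and gene-poor chromosomes, which left a log2 ratio of at least 0.45 on each. An extra copy of the whole chromosome stays open. Of the 13 with both arms measured, 12 had both arms at 1.4-fold or more, the exception being chromosome 19 in cell 13 (1.33 and 2.55). The pairs were chosen by the ratio of the whole chromosome, which favours pairs with both arms raised. That count therefore cannot tell a whole copy from changes of single arms. The 9 lower ratios were below 2-fold. They do not decide the question, because the ratio that a second copy gives in these cells could not be measured. Chromosome 8 and the chromosome 15 segment, which could have shown it, had no values. All 7 cells had totals below the median of 42448.5, between 20182 and 39255, and whether the pattern goes with a low yield was not tested.

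Segments of chromosomes were out of level too, in values picked after they were seen. In cell 21, chromosome 10 was at 2.71-fold beyond 100 Mb (687 counts, at most 1.33 in any other cell) and at 1.03 before it. In cell 10, 1q was at 1.87-fold, and in cell 2, 5p was at 2.31-fold. In cell 8, chromosome 4 was at 0.568 beyond 15 Mb, where the lowest other cell was at 0.832.

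Cell 22 lacked the profile shared by the other 25 cells, and the tests of scattered reads and of a wrong label were chosen only after its values were seen. Low depth alone is argued against: with every cell thinned to 20000 counts its mean correlation with the others was 0.0412, against 0.150 to 0.215 in the other cells. Reads scattered at random are argued against by its runs of positive bins, which were 1.34 times as long as shuffled ones. A mislabelled cell whose Dam fusion marks the opposite part of the genome cannot be told apart from other causes: its correlation with the mean of the others over 2644 windows of 1 Mb was 0.0602 (0.617 to 0.90 in the other cells), within the SD over chromosomes of 0.165, it was negative on 7 of 21 chromosomes (0 in every other cell), and gene-dense 19 (0.417), 17 (0.590) and 22:9 (0.571) were low relative to the other cells, but so were 11 (0.657) and 15 (0.571), and its gene-dense over gene-poor log2 ratio was still 0.14. Against the other autosomes of cell 22, gene-dense 16 (1.33) and 20 (1.46) stayed high and gene-poor 4 (0.756) and 13 (0.750) low. Gene-poor 5 (1.255) and 18 (1.205) were high instead, each at its highest level in any cell. Neither partial loss of the DNA of cell 22 nor a biological explanation was tested.

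Bins far apart on one chromosome varied together across cells, at 0.0199 for 20 Mb, and the test at 10 Mb was chosen only after its result was seen. Differences in depth as the whole cause are argued against, since the value was 0.0100 with all cells thinned to 20000 counts, above the highest permutation at 0.0034. Whole-chromosome shifts of single cells may account for much of it: after each cell was divided by its mean on the chromosome, the 20 Mb value was 0.0034, too close to the highest permutation, 0.0032, to decide whether anything remains. They are argued against as the whole cause at shorter distances, since the same division left 0.0076 at 10 Mb (highest permutation 0.0033), 0.0101 at 5 Mb (0.0029) and 0.0900 at 0.1 Mb.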
